A study of Homo sapiens with 124 samples.

How the data were processed

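The series holds 124 samples. Analysed here were the 60 peak lists of native ChIP-seq in 786-O kidney cancer cells, for H3K4me3, H3K27ac, H3K27me3, H3K9me3 and H3K36me3, each in EV (genotype wild type) and KO (labelled SETD2-/-) cells at day 0, day 5 and day 23 with 2 biological replicates. The day 5 and day 23 cells had received 300 nM decitabine for 24 h and the day 0 cells none, per the labels. The 4 input libraries and the 60 total RNA libraries of 7 cell lines were not analysed here.

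Paired reads of 50 bp were handled with Trim Galore, BWA, Picard and MACS2 on hg38, per the submitters' processing notes, which also name HISAT2 and deepTools. Versions of these tools are not given in the sources used here, nor is whether the input libraries served MACS2 as control. The deposited peak positions are the start and end of each peak in hg38, as MACS2 wrote them for each library without pooling replicates, per the labels. The deposited score of a peak is 10 times its -log10 q and was not used. The deposited fold enrichment is the ratio of a peak's signal to the local background of its own library, taken at the summit for the narrow marks and averaged over the region for the broad marks. It was used only within a library. The deposited -log10 p and -log10 q values, p-value and q-value of each peak against that background, were made by MACS2 per the file layout. The largest q was 0.0499 to 0.0500 in the narrow lists (H3K4me3, H3K27ac, H3K9me3) and 0.0997 in the broad lists (H3K27me3, H3K36me3), so the authors' limits appear to have been 0.05 and 0.1. All 60 lists are distinct files. No read counts or depths are in the lists, so the depth per sample is unknown, its precision cannot be given, and a difference in depth between libraries stays in every value. As a stand-in, the background fragments implied by p and fold at peak summits were computed after the data were seen, and ran from 3.22 to 6.94 for H3K4me3, 2.76 to 4.63 for H3K27ac and 4.91 to 18.0 for H3K9me3. They serve as description only. Replicate 2 had the larger covered length in 6 of 6 groups for H3K4me3, H3K27ac, H3K27me3 and H3K9me3 and in 5 of 6 for H3K36me3.

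Gene positions were taken from the RefSeq annotation of GRCh38.p14, which matches hg38, for 19974 protein-coding genes of chromosomes 1 to 22 and X. All 19 gene lists matched it in every member. The annotation gave no strand and no genome sequence was at hand. The plan had been to use transcription start sites, and this had to change: the promoter of a gene was taken as 2 kb either side of the gene end with the larger mean H3K4me3 cover over the 12 libraries of that mark (the left end for 8061 genes, the right for 7834, the mean of both ends for 4079). Among 7687 genes longer than 10 kb, H3K36me3 covered the body farther from the chosen end more in 78.1%, the direction that mark takes along transcription. Since H3K4me3 chose the end, this choice favours higher promoter values of that mark, and its size in each group was not measured. The body was the gene without 1 kb at both ends, for the 18069 genes of at least 3 kb. Repeat and CpG content of gained regions, also planned, needed the sequence and were left out.

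For each library the covered share of each feature, in percent, was the part of its bases under peaks. Features with at least 10% in at least 2 libraries of a mark were tested (14794 for H3K4me3, 12220 for H3K27ac, 7542 for H3K27me3, 4172 for H3K9me3, 10567 for H3K36me3). A linear model with 6 group means was fitted per mark with limma 3.58.1 in R 4.3.3, with robust moderation of the spread (6 residual degrees of freedom) and Benjamini-Hochberg adjustment per mark and comparison at 0.05. The 5 comparisons were KO against EV at day 0 and day 5 or day 23 against day 0 in EV and in KO, and an F test asked whether the 2 changes over days differed between genotypes. The day 0 libraries of EV serve 3 comparisons and so do those of KO, so these results are not independent. No untreated cells were harvested at day 23, so decitabine and time in culture are confounded. Gene lists were tested with limma camera with estimated inter-gene correlation, adjusted over all lists and comparisons of a mark (95 tests each for H3K4me3 and H3K27ac, 85 each for H3K27me3 and H3K36me3, 80 for H3K9me3), and with a preset correlation of 0.01 as an alternative. They were written before the data were examined, as were the comparisons, tests, thresholds and the rule for naming genes, apart from the departures given here. The lists are germline, interferon-stimulated, RNA-sensing, antigen presentation, HOX, developmental transcription factor, clustered protocadherin, chromosome 19 KRAB zinc finger, hypermethylated in renal cell carcinoma, renal epithelial, hypoxia, splicing factor, chromatin machinery, cell cycle, p53, ribosomal protein, blood, hepatocyte and neuron, and fibroblast and endothelial genes.

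Named genes are those past the threshold, with both libraries of a group above both of the other, among the 8 largest rises, the 8 largest falls and the 3 largest changes of each list, per mark and comparison, with SETD2, DNMT1, DNMT3A and DNMT3B in any case. From the top of these ranks 146 results were taken up, and 125 of them are printed. The other 21 were removed to shorten the text after the alternatives had been run, and all 21 had lost their call under at least 1 alternative, so the printed genes are a choice in favour of stable calls. A few further results that the rule allowed were left out for reasons unrelated to their values and are not counted here.

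Covered length, the genic share of H3K36me3 and the cover of H3K27me3 and H3K9me3 over bodies with at least 50% H3K36me3 in both untreated EV libraries were compared by exact permutation, two-sided, of genotype within day or day within genotype, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. Gained H3K4me3 regions had peaks overlapping by at least 1 bp in both later replicates and none in either untreated replicate, and lost regions the reverse. Shares of regions have 95% Wilson intervals, which cover counting error only. Figures were drawn with matplotlib 3.10.9.

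Replicate numbers were checked for pairing by the correlation, over genes, of deviations from the group means. It was over 0.1 in 5, 3, 9, 13 and 13 of the 15 pairs of groups for H3K4me3, H3K27ac, H3K27me3, H3K9me3 and H3K36me3. Since this was not so for every pair, and the labels give no shared batch, the numbers were not taken to pair the libraries. The lowest correlation of a pair was still positive in every mark, from 0.0207 (H3K27me3) to 0.0697 (H3K9me3). Replicate 2 also had the larger covered length in nearly every group, and the larger implied background in 6 of 6 groups for H3K4me3, H3K27ac and H3K9me3. An effect shared by replicate number therefore stays possible, and results with that number as a block are given with the alternatives. The block changes the verdict on covered length for H3K4me3 and H3K9me3 and on the genic share of H3K36me3. It also changes that on the renal H3K27ac and interferon H3K36me3 lists in KO.

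The limma step was tested on simulated data for KO against EV at day 0, with residuals of the real libraries and 200 genes shifted by 20 or 40 points. It recovered 23 and 70% of them for H3K4me3, 7 and 41% for H3K27ac, 0 and 1% for H3K27me3, 29 and 52% for H3K9me3 and 22 and 51% for H3K36me3. False calls made up 9.71, 5.88, 83.3, 6.90 and 16.1% of the calls, where the 83.3% for H3K27me3 rests on 5 false calls and 1 recovered gene. The residuals were shuffled within a gene after a first simulation, whose mirrored residuals of 2 replicates gave false calls, and this removes differences in depth between libraries, so the simulation does not cover those. For day 23 in KO, camera gave a simulated list of 40 genes shifted by 20 points an adjusted p from 9.58e-05 to 0.00517 over the marks and called 0 unchanged lists.

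Alternatives set before the data were examined were peaks with -log10 q of at least 5, equal covered length (peaks of highest -log10 q kept until each library covers as much as the smallest of its mark), a narrower promoter window of 1 kb with the untrimmed body, the arcsine square root of the share, the replicate number as block, no filter, number of peaks in place of covered length, bodies with at least 80% H3K36me3, overlap of at least 0.5 of either peak, and each library left out in turn. Equal covered length removes any change in total cover, real or technical, so gains and losses are drawn toward balance by construction. With a library left out, its group holds 1 library, which is assumed to vary like the other groups. Chosen after the data were seen were the mean of both gene ends, leaving out chromosomes 13 and 14, the alternatives of the list tests other than the preset correlation, and those of the share of gained regions near a gene end.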

Results

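Native ChIP-seq peak lists of 5 histone marks were compared in 786-O cells, an established line of clear cell kidney cancer that lacks VHL. The labels divide the cells into EV, with wild-type SETD2, and KO, labelled as lacking SETD2, the enzyme that places H3K36me3 over transcribed genes. These names are used here as the labels give them. Cells were harvested untreated at day 0, or at day 5 and day 23 after a 24 h exposure to 300 nM decitabine, which traps DNA methyltransferases and lowers DNA methylation. Each of the 6 groups of a mark held 2 biological replicates, so 60 libraries were analysed. H3K4me3 marks active promoters, H3K27ac active promoters and enhancers, H3K27me3 Polycomb-silenced genes, H3K9me3 heterochromatin and H3K36me3 transcribed gene bodies. The value reported for a gene is its covered share, the percent of its promoter (H3K4me3, H3K27ac, H3K27me3) or gene body (H3K9me3, H3K36me3) lying under peaks of a library, given as mean ± SD with n = 2 per group. The peak lists give no read counts, so the sequencing depth is unknown and no interval for counting error can be given. Libraries held 38033 to 82170 peaks of H3K4me3, 46518 to 64068 of H3K27ac, 65461 to 116510 of H3K27me3, 91846 to 199028 of H3K9me3 and 51841 to 80660 of H3K36me3.

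The SETD2 gene itself carried H3K4me3 over 79.9 to 91.1% of its promoter in all 12 libraries of that mark. Its body was covered by H3K36me3 over 66.8 to 79.9% in the 6 EV libraries and 36.7 to 66.9% in the 6 KO libraries. Peaks at this locus cannot show whether the protein is lost, so they do not check the labels. DNMT1, the maintenance DNA methyltransferase that decitabine traps, had H3K36me3 over 97.6 to 100% of its body in all 12 libraries. DNMT3B, a de novo DNA methyltransferase, had 71.5 to 82.3% in EV and 27.6 to 74.3% in KO, and the DNMT3A body had at most 4.45%.

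The total length of genome under peaks was compared between the genotypes and days for each mark, which the design asked before single genes. H3K36me3 covered 280.1 ± 4.57 Mb in EV and 218.2 ± 12.2 Mb in KO at day 0, 314.8 ± 8.36 and 183.3 ± 24.3 Mb at day 5, and 287.2 ± 23.9 and 198.1 ± 28.8 Mb at day 23. The KO to EV ratio over the 3 days was 0.677 for H3K36me3 (exact permutation test within day, two-sided, p = 0.00926, the smallest the 216 relabellings allow). It was 0.719 for H3K27me3 (exact permutation p = 0.00926), 0.593 for H3K9me3 (p = 0.0278), 0.783 for H3K4me3 (p = 0.0556) and 0.890 for H3K27ac (p = 0.269). The H3K9me3 result passed 0.05 with the whole set but gave exact permutation p between 0.0556 and 0.0741 without EV day 0 replicate 2, EV day 23 replicate 1, EV day 23 replicate 2, KO day 0 replicate 1 or KO day 23 replicate 1. Without EV day 0 replicate 1, EV day 23 replicate 1, KO day 0 replicate 2 or KO day 23 replicate 2 the H3K4me3 ratio passed, at exact permutation p between 0.0370 and 0.0463. From day 0 to day 23 the ratio was 1.45 for H3K4me3, 1.17 for H3K27ac and 0.595 for H3K27me3, each with an exact permutation p of 0.0556, which is the smallest that the 36 relabellings allow. The H3K27me3 ratio was 0.169 with stricter peaks (exact permutation p = 0.111). With stricter peaks the KO to EV difference did not pass for H3K27me3 (ratio 0.457, exact permutation p = 0.213), H3K36me3 (0.120) or H3K9me3 (0.0556). Their 3 ratios, means over the 3 days, nevertheless lay further from 1 than with all peaks. At day 0 alone, stricter H3K36me3 peaks covered 94.3 and 124.7 Mb in the EV replicates and 104.2 and 139.7 Mb in KO. For H3K9me3 these values were 121.3 and 170.1 Mb in EV and 126.0 and 177.1 Mb in KO. Untreated KO was therefore not lower on average in these marks, while for H3K27me3 it was (13.7 and 48.9 Mb against 51.4 and 84.2 Mb in EV). Counting peaks in place of length, the KO to EV difference passed for H3K4me3 (exact permutation p = 0.00926). The day 23 to day 0 ratio was 0.726 for H3K9me3 (p = 0.222) and 0.962 for H3K36me3 (p = 0.667) by the same exact permutation test. The H3K36me3 ratio had no stable direction, since it was +0.02 on the log2 scale without KO day 23 replicate 1 and +0.28 for the number of peaks. The correlation across genes, which are not independent replicates, was 0.946 to 0.982 between H3K4me3 replicates and 0.8002 to 0.929 between its groups, and 0.886 to 0.924 and 0.663 to 0.860 for H3K27ac. For the other marks the ranges overlapped: 0.762 to 0.892 and 0.387 to 0.812 for H3K27me3, 0.795 to 0.966 and 0.463 to 0.886 for H3K9me3, and 0.925 to 0.957 and 0.601 to 0.934 for H3K36me3.

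**Figure D1:**
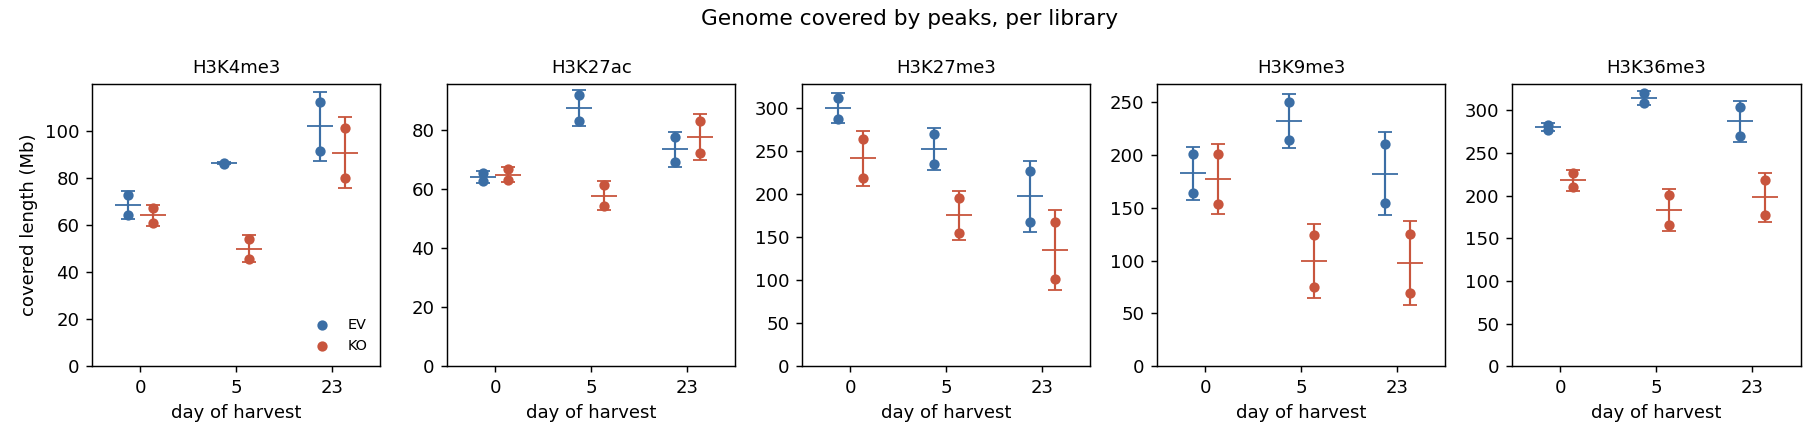
Length of genome covered by peaks in Mb for each mark (panels), by day of harvest, in EV (blue) and KO (red) libraries, with each point a library and bars the mean ± SD of 2 replicates. KO libraries of H3K36me3 lie below the EV libraries of the same day on all 3 days, at 218.2, 183.3 and 198.1 Mb on average.

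Untreated KO cells were compared with untreated EV cells to see which genes differ in chromatin where SETD2 is labelled as lost. PAX2, the transcription factor of the developing kidney (chromosome 10, 100735396 to 100829944, hg38), had no H3K27ac over its promoter in EV and 85.5 ± 8.91% in KO, and its H3K4me3 was 0% against 76.6 ± 11.6%. The transcription factor gene POU3F3 (chromosome 2, 104853276 to 104927773) showed the reverse direction: H3K27ac fell from 100 to 0%, H3K4me3 from 100 to 19.4 ± 14.2%, and H3K27me3 rose from 0 to 100%. SLC17A3, a urate transporter of the proximal tubule, rose in H3K4me3 from 3.52 ± 4.99 to 74.1 ± 4.56%, and the tight-junction gene CLDN2 from 10.9 ± 15.4 to 95.3 ± 6.72%. MDGA2 and LRFN5, neuronal adhesion genes on chromosome 14, went from 0 to 90.8 ± 0.53% and from 10.6 ± 0.97 to 97.6 ± 3.38%. A pair of p53 target genes rose in H3K27ac, EDA2R from 0 to 68.1 ± 8.27% and the cell-cycle inhibitor CDKN1A from 8.79 ± 0.09 to 73.5 ± 1.54%, and in H3K4me3, from 0 to 67.2 ± 0.00% and from 12.01 ± 1.18 to 50.8 ± 5.27%. Among HOX genes, HOXB5 fell in H3K27ac from 74.7 ± 2.83 to 6.71 ± 9.49% and HOXA7 from 59.8 ± 0.09 to 0%. HOGA1, a kidney and liver enzyme of hydroxyproline breakdown, gained H3K27ac (0 to 83.1 ± 1.15%), and SLC14A2, the urea transporter of the renal medulla, lost it (93.9 ± 8.64 to 0%). All of these passed the limma test, with adjusted p from 3.39e-06 (POU3F3, HOGA1 in H3K27ac) to 0.00303 (CDKN1A in H3K4me3), and PAX2 had 2.1e-05 in H3K27ac and 0.00209 in H3K4me3. At equal covered length the H3K4me3 calls of EDA2R and CDKN1A and the H3K27ac call of HOXB5 were lost, at adjusted p of 0.0583, 0.0593 and 0.0859, the highest of their alternatives, whose lowest were 2.1e-05, 0.00131 and 0.000268. Their changes there were 67.2, 25.6 and -74.7 points, so those of EDA2R and HOXB5 had not shrunk.

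Over gene bodies, H3K36me3 was lower in KO at GPX3, a kidney-rich antioxidant enzyme (90.9 ± 11.7 to 4.33 ± 6.12%), ANPEP, a brush-border peptidase (85.6 ± 4.17 to 0%), GNMT (100 to 0%), the interferon regulator IRF7 (100 to 0%) and the zinc finger gene ZNF547 (75.1 ± 5.15 to 1.91 ± 2.69%). It was higher at SLC7A2, an arginine transporter (0 to 94.6 ± 0.47%, limma adjusted p = 6.27e-06), and at MYEOV (0 to 100%). Trimmed bodies of genes close to the 3 kb limit are short, so 1 peak can move their share between 0 and 100%. Chromosome 19 KRAB zinc finger genes, repressors of transposable elements, averaged 54.6% in EV and 39.0% in KO over 217 members, of which 71 were lower and 2 higher (77 and 2 adjusted over the list alone, limma camera adjusted p = 0.973). The mean difference of -15.6 points was -7.40 at equal covered length and -3.29 with stricter peaks. H3K9me3 covered the body of PCDHB3, a clustered protocadherin, by 89.1 ± 15.4% in EV and 0% in KO, and that of PRR20B and PRR20A, near-identical neighbours that reads can confuse, by 100 and 0%. FAM43A and SFMBT2 gained H3K27me3 (0 to 100%) and ZNF618 lost it (100 to 0%). With stricter peaks the adjusted p of GNMT, IRF7, GPX3, MYEOV and ZNF547 was 0.846, 0.846, 0.0907, 0.771 and 1, at changes of -50, -50, -73.2, 50 and 0 points, and that of ANPEP at equal covered length 1, at a change of 0. Those are the highest of the alternatives, and the lowest were 1.15e-09, 0.00025, 0.000979, 3.04e-06, 0.000112 and 2.77e-05. For H3K27me3 the stricter peaks gave 0.152 for FAM43A, 0.0528 for POU3F3 and 0.126 for ZNF618, with lowest values of 4.21e-05, 4.85e-06 and 2.37e-05, while the changes stayed at 100, 100 and -100 points. With equal covered length MYEOV still changed by 100 points (0.136), IRF7 by -50 (0.300) and ZNF547 by 0 (1).

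At the threshold of 0.05 this comparison called 972 of 14794 H3K4me3 promoters (228 higher and 744 lower in KO), 1240 of 12220 H3K27ac promoters (226 and 1014), 1138 of 7542 H3K27me3 promoters (248 and 890), 461 of 4172 H3K9me3 bodies (299 and 162) and 3098 of 10567 H3K36me3 bodies (284 and 2814). When every library of a mark was trimmed to the same covered length, the H3K36me3 split became 649 higher and 618 lower and the H3K27me3 split 216 and 366. Trimming removes any difference in total cover, real or technical, so these 2 splits cannot show whether a general loss in KO was real. Of the H3K4me3, H3K27ac and H3K9me3 calls, 27.8, 16.7 and 56.0% were higher in KO after trimming, against 23.5, 18.2 and 64.9% before. H3K4me3 and H3K27ac calls thus stayed mostly lower in KO. The H3K27ac covered length at day 0 was 64.0 ± 2.09 Mb in EV and 64.9 ± 2.52 Mb in KO. Leaving out in turn EV day 0 replicate 1, EV day 0 replicate 2, KO day 0 replicate 1 or KO day 0 replicate 2 gave 392 to 569 H3K4me3 genes, 373 to 576 for H3K27ac, 380 to 810 for H3K27me3, 122 to 174 for H3K9me3 and 1551 to 2247 for H3K36me3. In data simulated for this comparison, 83.3% of the H3K27me3 calls were false (5 false, 1 recovered) and 1% of its changes of 40 points was recovered. By this simulation the calls of this mark are the least secure of the 5. It held no change above 40 points, so it gives no error rate for larger ones.

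Genes covered by H3K36me3 in EV remained largely covered in KO. Of 18069 gene bodies, 6168 were covered by at least 50% in both untreated EV libraries and 4588 in both KO libraries, and 4410 were in both sets, against 1566 if the sets were independent. KO libraries had 1.05 points more of their H3K36me3 bases inside genes, which did not pass (exact permutation within day, p = 0.0741), although it did, at 1.21 to 1.47 points and exact permutation p of 0.0370 to 0.0463, without EV day 5 replicate 1, EV day 23 replicate 1 or KO day 5 replicate 2. With stricter peaks the difference was 2.30 points (exact permutation p = 0.00926), and at equal covered length 0.429 (p = 0.398). Over the 6168 bodies, H3K27me3 averaged 0.207 ± 0.0547% in EV and 0.120 ± 0.0412% in KO at day 0, and H3K9me3 2.77 ± 0.253 and 3.79 ± 0.585%. Neither difference over the 3 days passed, at -0.101 points (exact permutation p = 0.556) and -0.778 points (p = 0.352). At equal covered length both were positive instead, at 0.0880 and 0.479 points with an exact permutation p of 0.00926. Trimming cut each library to the smallest of its mark, KO day 23 replicate 1 at 101.6 Mb (H3K27me3) and 69.2 Mb (H3K9me3). EV libraries, with up to 311.4 and 250.1 Mb, lost more on average, which by itself raises KO minus EV. The trimmed values therefore cannot show that either mark spread into these bodies in KO. With stricter peaks the H3K27me3 difference was 0.00957 (exact permutation p = 0.315). Without EV day 23 replicate 2 it was 0.0177 (exact permutation p = 0.898), without KO day 23 replicate 1 -0.0167, without KO day 23 replicate 2 -0.186 and without EV day 23 replicate 1 -0.221. The H3K9me3 difference ran from -0.314 (without KO day 5 replicate 1) to -1.24 (without KO day 5 replicate 2), with -0.454 without KO day 23 replicate 1 and -0.488 without EV day 23 replicate 2.

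In EV cells 5 days after decitabine, promoter marks were gained at single genes such as HOXA3, HOXD9 and COL5A1. H3K4me3 over HOXA3 went from 0 to 100%, over HOXD9 from 0 to 65.9 ± 2.35%, over the fibrillar collagen gene COL5A1 from 0 to 84.8 ± 21.4% and over TWIST1, a mesenchymal transcription factor, from 0 to 78.1 ± 5.21%. The chemokine receptor gene CXCR4, a HIF target, fell from 78.0 ± 5.87 to 10.7 ± 15.1%, and GRM7 from 63.4 ± 1.06 to 0%. H3K27ac appeared at CHRDL2 (80.7 ± 11%) and TRIML2 (76.6 ± 5.85%) and fell at FUT7, from 80.8 ± 4.31 to 7.78 ± 10.6%. H3K36me3 rose over the stress-response factor ATF5 (2.72 ± 1.98 to 100%) and fell over the kidney cadherin CDH6 (87.4 ± 1.14 to 14.98 ± 1.10%) and over IRF7 (100 to 10.96 ± 15.5%). H3K9me3 spread over ELOA2 (0 to 100%) and CCER2 (0 to 98.3 ± 1.17%). Limma adjusted p ran from 1.15e-05 (CDH6) to 0.00376 (CCER2) over these genes. At equal covered length the calls of TWIST1, CHRDL2, ATF5, IRF7 and CDH6 were lost, at adjusted p of 1, 0.237, 0.562, 0.557 and 0.0800 and changes of 0, 41.6, 50, -50 and -25.9 points, and with stricter peaks those of ATF5 (0.756, 50 points) and IRF7 (0.798, -50 points), where the lowest values over the alternatives were 7.22e-05, 0.000255, 9.03e-05, 0.00344 and 8.46e-07.

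Of the HOX list, 36 promoters were tested for H3K4me3, and their mean rose from 62.9 to 80.3%, with 10 members up and 0 down over all genes and 17 up adjusted over the list alone. The limma camera test with estimated correlation did not set the list apart (adjusted p = 0.805). The interferon-stimulated promoters averaged 24.6% H3K27ac untreated and 24.1% at day 5 (1 up, 0 down, the same adjusted over the list alone, limma camera adjusted p = 0.502), a change of -0.547 points that became -10.2 at equal covered length, 0.849 with stricter peaks, and 0.378, -1.47 and -0.269 without EV day 0 replicate 1, EV day 0 replicate 2 and EV day 5 replicate 1, so it has no stable direction or size. Without EV day 5 replicate 2 it was -0.826. For this day 5 comparison in EV the calls were 873 for H3K4me3 (594 up, 279 down), 539 for H3K27ac (469 and 70), 33 for H3K27me3 (9 and 24), 2027 for H3K9me3 (1965 and 62) and 371 for H3K36me3 (284 and 87). With equal covered length the splits were 323 and 372, 444 and 1353, 63 and 84, 233 and 44, and 166 and 182. Without 1 of EV day 0 replicate 1, EV day 0 replicate 2, EV day 5 replicate 1 or EV day 5 replicate 2 the counts ran from 238 to 380, 83 to 236, 1 to 19, 70 to 955 and 78 to 166. Some libraries outside the comparison also moved the counts, since they enter the pooled spread and the filter that sets which genes are tested. The H3K27me3 count was 71 or 60 without EV day 23 replicate 1 or 2, 7 without KO day 5 replicate 1 or 2, and 10 without KO day 23 replicate 1 or 2.

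By day 23 the EV cells carried active marks at interferon-stimulated genes, which encode the antiviral response. H3K27ac over MX2 rose from 0 to 65.0 ± 9.63%, over OAS2 from 0 to 55.7 ± 4.51% and over XAF1 from 35.0 ± 2.19 to 98.9 ± 1.61%. H3K36me3 rose over the bodies of XAF1 (0 to 97.2 ± 0.15%), MX2 (0 to 93.3 ± 9.43%), IFI6 (4.80 ± 6.78 to 100%) and the RNA sensor regulator DHX58 (4.61 ± 6.51 to 97.1 ± 1.42%). H3K4me3 rose at IFITM1 (0 to 96.6 ± 1.34%), XAF1 (29.4 ± 5.14 to 100%), IRF7 (22.5 ± 8.82 to 88.0 ± 9.99%) and OAS2 (24.5 ± 7.02 to 77.7 ± 2.03%). The 45 listed interferon-stimulated promoters averaged 25.6 and 23.7% H3K27ac in the untreated replicates and 46.5 and 50.6% at day 23. Of these, 18 rose and 0 fell over all genes and 31 rose adjusted over the list alone, and limma camera set the list apart (adjusted p = 0.0290). Without EV day 0 replicate 2 that adjusted p was 0.116, the highest when 1 library was left out, and the lowest was 0.0487, while 11 of the 12 libraries gave values above 0.05. The H3K36me3 rise of the list, 38.1 to 74.4% with 29 up and 0 down (31 up adjusted over the list alone), had a camera adjusted p of 0.143, and 0.0217 at equal covered length. For H3K4me3, 28 of 44 rose (31 adjusted over the list alone) and none fell, from 48.5 to 73.5% (limma camera adjusted p = 0.805).

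Other genes changed with them in EV at day 23. Keratin KRT17 gained H3K4me3 (0 to 100%) and lost H3K27me3 (100 to 2.55 ± 3.61%), and COL5A1 gained H3K4me3 and H3K27ac (both 0 to 100%). The cytokine gene LIF gained H3K4me3 (0 to 100%), as did the germline genes TDRD9 (0 to 70.1 ± 2.55%) and BOLL (0 to 50.6 ± 9.48%) and the forebrain factor SIX3 (5.15 ± 7.28 to 65.8 ± 5.64%). The methyl-DNA reader ZBTB38 lost H3K4me3 (82.3 ± 0.58 to 0%) and H3K27ac (96.1 ± 5.48 to 0%), and the CDK4/6 inhibitor gene CDKN2C lost H3K27ac (94.9 ± 7.23 to 9.96 ± 10.9%). H3K4me3 fell at the potassium channel gene KCNJ16 (93.9 ± 3.71 to 5.31 ± 7.51%) and the proximal tubule scaffold PDZK1 (88.7 ± 0.78 to 10.4 ± 14.7%). H3K36me3 fell over CDH6 (87.4 ± 1.14 to 2.55 ± 1.13%) and TIMD4 (90.7 ± 4.18 to 3.23 ± 1.26%) and rose over MYEOV (0 to 100%). H3K27me3 rose at ALX4 (7.42 ± 10.5 to 100%) and fell at RUNX3 (100 to 0%). Limma adjusted p ran from 9.17e-07 for IFITM1 to 0.00700 for KRT17 in H3K27me3. Equal covered length ended the H3K4me3 calls of LIF, KCNJ16 and IRF7 (limma adjusted p = 0.344, 0.332 and 1) and the H3K36me3 call of MYEOV (0.502), at changes of 50, -45.6, 0 and 50 points, with lowest values of 3.72e-06, 8.05e-05, 0.000332 and 3.04e-06. Stricter peaks ended the H3K36me3 calls of DHX58, MX2, XAF1 and MYEOV (0.770, 0.328, 0.314 and 0.770, at changes of 48.0, 62.3, 97.2 and 50 points, with lowest values of 4.5e-05, 2.49e-05, 8.62e-06 and 3.04e-06), and averaging both gene ends that of RUNX3 in H3K27me3 (0.0718, -50 points, lowest 0.00211).

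Over all genes, day 23 against day 0 in EV gave 2343 calls for H3K4me3 (2139 up, 204 down), 543 for H3K27ac (335 and 208), 506 for H3K27me3 (143 and 363), 37 for H3K9me3 (20 and 17) and 2431 for H3K36me3 (976 and 1455). After trimming to equal covered length the splits were 691 and 318, 266 and 368, 237 and 153, 25 and 18, and 556 and 476. Leaving out in turn EV day 0 replicate 1, EV day 0 replicate 2, EV day 23 replicate 1 or EV day 23 replicate 2 gave 998 to 1777, 176 to 359, 112 to 339, 0 to 48 and 1210 to 1850 calls. The H3K27me3 count also fell to 289 without KO day 0 replicate 1 or 2 and to 323 or 324 without KO day 5 replicate 1 or 2. The H3K9me3 count was 13 without EV day 5 replicate 1 or 2 or KO day 0 replicate 1 or 2, and the 0 came from limma without EV day 0 replicate 2, where 376 genes had an unadjusted p under 0.05.

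KO cells at day 5 lost marks at kidney epithelial genes. H3K27ac over PAX2 fell from 85.5 ± 8.91 to 4.24 ± 5.99%, over HOGA1 from 83.1 ± 1.15 to 0%, over PDZK1 from 82.2 ± 13.7 to 5.30 ± 7.50% and over SLC17A3 from 72.7 ± 15.7 to 0%. These are compared with the same untreated KO libraries in which PAX2, HOGA1 and SLC17A3 were higher than in EV. H3K4me3 fell at CLDN2 (95.3 ± 6.72 to 0%), KCNJ16 (100 to 4.22 ± 5.98%), GPR15 (94.1 ± 1.82 to 4.92 ± 6.97%), PDZK1 (88.7 ± 14.9 to 4.44 ± 6.28%) and SLC17A3 (74.1 ± 4.56 to 0%). H3K36me3 fell over CDH6 (86.7 ± 1.27 to 0.32 ± 0.01%) and HOXD10 (100 to 2.46 ± 3.47%). CDKN2C (95.7 ± 6.13 to 1.77 ± 2.51%) and FSD2 (92.9 ± 0.53 to 6.88%) lost H3K27ac, and the limb factor TBX3 gained it (0 to 68.7 ± 3.98%). LIF (0 to 72.9 ± 18.6%) and BNC1 (6.56 ± 9.28 to 68.2 ± 15.9%) gained H3K4me3. H3K9me3 fell over the zinc finger genes ZNF722 (75.7 ± 3.63 to 13.3 ± 5.65%), ZNF776 (91.4 ± 1.78 to 30.5 ± 8.31%) and ZNF614 (77.3 ± 4.40 to 18.2 ± 3.36%) and rose over PCDHB3 (0 to 67.2 ± 10.96%). Limma adjusted p ran from 1e-06 (HOXD10 and CDH6) to 0.00849 (PCDHB3), and PCDHB3 had 0.0705 without KO day 0 replicate 2, at an unchanged 67.2 points, the highest of its alternatives (lowest 0.00348). Equal covered length ended the calls of LIF (0.0871), BNC1 (0.0903), PDZK1 in H3K27ac (0.0770), HOXD10 (1) and ZNF722 (0.699), at changes of 72.9, 68.2, -76.9, 0 and -10.1 points, and stricter peaks that of HOXD10 (1, 0 points). Lowest values for these were 4.79e-05, 0.00147, 0.000289, 3.74e-07 and 0.000486.

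The 16 tested renal epithelial promoters averaged 48.2 and 45.0% H3K27ac in the untreated KO replicates and 14.3 and 15.2% at day 5, with 6 down and 0 up (10 down adjusted over the list alone), and limma camera set them apart (adjusted p = 0.0290). Without KO day 0 replicate 1 the adjusted p was 0.281, and leaving out any of the 12 libraries moved it above 0.05, from 0.0544 upwards. Their H3K36me3 means over 17 bodies, 48.9 and 19.8% (8 down, 0 up, 9 down adjusted over the list alone), did not stand apart (limma camera adjusted p = 0.699), except at equal covered length (0.0479), and with stricter peaks the change was -56.1 points over 10 bodies (0.0954). Interferon-stimulated promoters averaged 18.7% H3K27ac at day 5 against 27.5% untreated, with 1 up and 4 down, 1 and 5 adjusted over the list alone (limma camera adjusted p = 0.737), and changed by -7.60 points at equal covered length, where the EV list changed by -10.2. The calls were 3039 for H3K4me3 (214 up, 2825 down), 627 for H3K27ac (206 and 421), 92 for H3K27me3 (20 and 72), 959 for H3K9me3 (245 and 714) and 1501 for H3K36me3 (136 and 1365). Trimmed to equal covered length, the last 4 split into 237 and 265, 79 and 59, 449 and 246, and 262 and 414. The H3K4me3 calls stayed mostly down, with 11.2% up at equal covered length against 7.04% with all peaks. Leaving out in turn KO day 0 replicate 1, KO day 0 replicate 2, KO day 5 replicate 1 or KO day 5 replicate 2 gave 646 to 2971, 176 to 287, 5 to 12, 152 to 1377 and 701 to 1289 calls. The H3K27me3 count was 58 without EV day 0 replicate 1 or 2 or EV day 5 replicate 1, 57 without EV day 5 replicate 2, and 56 or 54 without EV day 23 replicate 1 or 2.

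At day 23 KO cells combined gained interferon marks with low kidney marks. H3K36me3 rose over IFI6 and IRF7 (both 0 to 100%), IFI44L (0 to 98.7 ± 1.83%) and the RNA sensor IFIH1 (7.65 ± 2.12 to 82.9 ± 3.32%). H3K27ac rose at IFI6 (0 to 89.8 ± 10.7%), IFI44L (11.7 ± 16.5 to 92.4 ± 5.80%) and MX2 (0 to 80.2 ± 8.13%), and H3K4me3 at GBP5 (0 to 99.7 ± 0.41%), OAS2 (0 to 73.7 ± 11.3%), BATF2 (0 to 68.9 ± 2.07%) and MX2 (0 to 63.6 ± 3.94%). COL5A1 and LIF gained H3K4me3 (0 to 100%), as did MAGEA3 (0 to 48.8 ± 6.93%), a cancer-testis gene with close paralogs that share reads. IL17B (4.31 ± 6.10 to 95.8 ± 3.29%) gained H3K27ac. PAX2 fell in H3K27ac (85.5 ± 8.91 to 0%) and H3K4me3 (76.6 ± 11.6 to 6.71 ± 9.49%), against the untreated KO libraries in which it exceeded EV. PDZK1 (82.2 ± 13.7%), SLC17A3 (72.7 ± 15.7%), CLDN2 (94.8 ± 7.34%) and ZBTB38 (96.4 ± 5.13%) fell to 0% in H3K27ac, and KCNJ16 (100%) and CLDN2 (95.3 ± 6.72%) to 0% in H3K4me3. H3K36me3 fell over CDH6 (86.7 ± 1.27 to 0%), VCAM1 (90.9 ± 3.03 to 11.1 ± 4.92%) and TIMD4 (96.6 ± 0.68 to 0%). H3K9me3 rose over PRR20B (0 to 59.9 ± 10.2%) and fell over ZNF614 (77.3 ± 4.40 to 20.1 ± 1.53%) and ZNF595 (96.7 ± 1.16 to 42.3 ± 9.82%). Limma adjusted p ran from 9.79e-07 (CDH6) to 0.00374 (MAGEA3). Equal covered length ended the calls of LIF, MAGEA3, ZNF614 and IRF7 (0.0648, 1, 0.0756 and 0.0582), at changes of 100, 0, -40.2 and 100 points, and stricter peaks that of IRF7 (0.776, 50 points). Lowest values for these genes were 3.72e-06, 0.000609, 0.000724 and 0.000299.

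In KO the interferon-stimulated promoters averaged 26.6 and 28.3% H3K27ac untreated and 59.0 and 63.8% at day 23, with 24 up and 0 down (34 up and 2 down adjusted over the list alone, limma camera adjusted p = 0.0290). Their H3K36me3 means were 33.8 and 79.6%, with 32 up and 0 down (35 up adjusted over the list alone), and camera gave 0.0493, with 0.0667 under stricter peaks and 0.00344 at equal covered length. H3K4me3 rose at 27 of 44 (32 adjusted over the list alone) and fell at none, from 47.7 to 76.3% (limma camera adjusted p = 0.718). Renal epithelial promoters averaged 17.9% H3K27ac against 46.6% untreated, with 7 down and 0 up (9 down adjusted over the list alone, limma camera adjusted p = 0.0290, and 0.0519 at equal covered length). Leaving out EV day 0 replicate 2 gave the highest interferon H3K27ac value, 0.116 (lowest 0.0487). The other highest values were 0.191 for interferon H3K36me3 without KO day 0 replicate 2 and 0.281 for renal H3K27ac without KO day 0 replicate 1, and both results stayed above 0.05, from 0.0612 and 0.0544, whichever of the 12 libraries was left out. Over all lists, limma camera with estimated correlation made 4 calls for H3K27ac, the interferon-stimulated list at day 23 in both genotypes and the renal list at both days in KO, 1 for H3K36me3, the interferon-stimulated list at day 23 in KO, and 0 for H3K4me3, H3K27me3 and H3K9me3, where 5, 1 and 0 tests had an unadjusted p under 0.05. With the preset correlation it made 18, 23, 21, 5 and 22, of which those 5 hold with the estimated correlation. In EV the renal promoters went from 40.3 to 25.3% by day 23 (5 down, 0 up, 7 down and 2 up adjusted over the list alone, limma camera adjusted p = 0.369), and by -28.4 points over 12 promoters at equal covered length (0.0854).

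**Figure D2:**
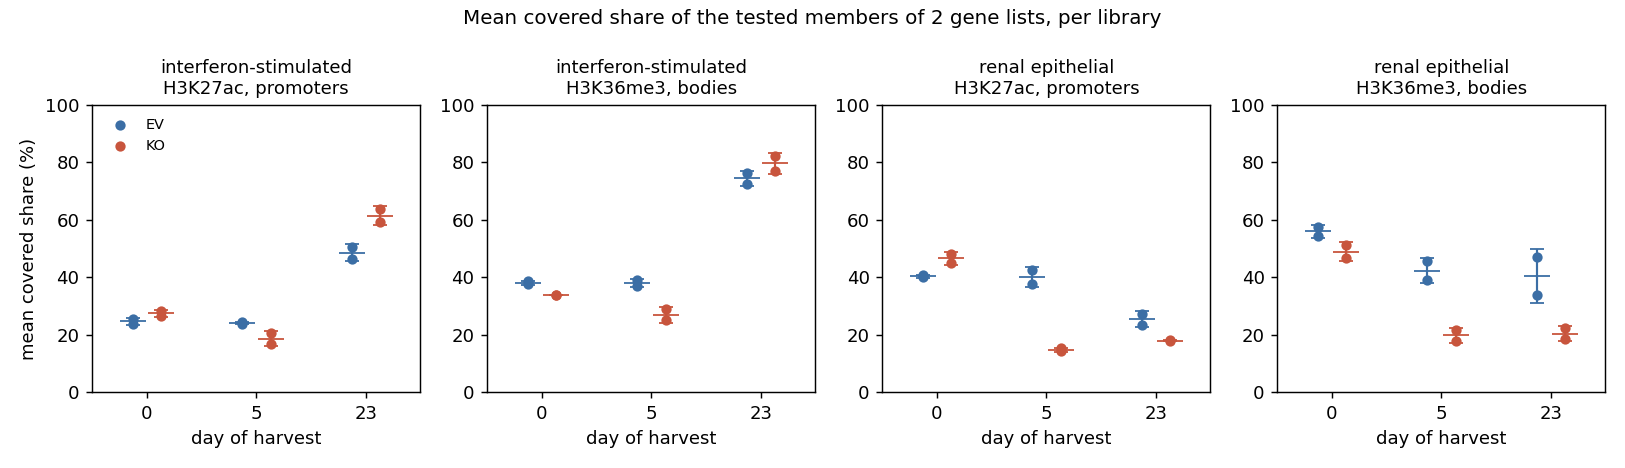
Mean covered share in percent of the tested members of the interferon-stimulated and renal epithelial lists, for H3K27ac over promoters and H3K36me3 over bodies, by day of harvest, in EV (blue) and KO (red). Points are libraries and bars the mean ± SD of 2 replicates, and interferon-stimulated H3K27ac stood at 46.5 and 50.6% in EV and 59.0 and 63.8% in KO at day 23.

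Day 23 in KO called 1528 genes for H3K4me3 (1136 up, 392 down), 1047 for H3K27ac (768 and 279), 423 for H3K27me3 (101 and 322), 605 for H3K9me3 (29 and 576) and 1635 for H3K36me3 (315 and 1320). Equal covered length gave splits of 468 and 411, 480 and 468, 147 and 125, 176 and 167, and 394 and 496. Leaving out in turn KO day 0 replicate 1, KO day 0 replicate 2, KO day 23 replicate 1 or KO day 23 replicate 2 gave 533 to 1646, 461 to 857, 66 to 291, 57 to 558 and 951 to 1413 calls. The day 23 comparisons of EV and KO share no library, but they share the filter and the spread estimated for each gene. Genes of low spread are called more readily in both, so the numbers in parentheses, expected for independent calls, are no chance level. Genes called up in both numbered 607 for H3K4me3 (164), 174 for H3K27ac (21.1), 15 for H3K27me3 (1.92), 2 for H3K9me3 (0.139) and 122 for H3K36me3 (29.1). Genes called down in both numbered 85 (5.41), 71 (4.75), 88 (15.5), 4 (2.35) and 740 (182).

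H3K4me3 regions absent from both untreated replicates and present in both later ones numbered 13829 in EV at day 5, 22176 in EV at day 23, 5402 in KO at day 5 and 18721 in KO at day 23. Regions lost were 3111, 2952, 6686 and 3233. The other ways of pairing the same 4 libraries gave 267 to 1626. At equal covered length the gained counts were 374, 229, 7744 and 502 and the lost counts 1398, 1587, 329 and 1167, so which of gained and lost was larger changed for all 4 comparisons. Since trimming removes any change in total cover, this reversal cannot tell a real change from a difference in depth. Leaving out EV day 5 replicate 1 or 2 gave 26455 and 31078 gained, EV day 23 replicate 1 or 2 42176 and 37260, KO day 5 replicate 1 or 2 17868 and 14532, and KO day 23 replicate 1 or 2 39512 and 32535, since a single replicate then sufficed. Leaving out untreated replicate 1 or 2 raised the lost counts to 7444 and 6443 in EV at day 5, 6745 and 6127 in EV at day 23, 11376 and 11563 in KO at day 5, and 5774 and 6096 in KO at day 23. Without EV day 5 replicate 1 the loss there was 4817, and without EV day 23 replicate 2 it was 5065. Gained regions lay within 2 kb of a gene end in 6.45% (EV day 5, 95% Wilson interval 6.05 to 6.87), 9.37% (EV day 23, 8.99 to 9.76), 7.15% (KO day 5, 6.49 to 7.86) and 7.95% (KO day 23, 7.57 to 8.35). Regions present in all 4 libraries did so in 40.6, 41.6, 53.9 and 45.5%. Their median widths were 2276 to 2595 bp, against 632 to 868 bp for gained regions. A wider region reaches a gene end more readily, so these shares are not like for like. With equal covered length the gained shares were 8.82% (95% Wilson interval 6.35 to 12.13), 37.99% (31.95 to 44.4), 7.33% (6.77 to 7.94) and 19.7% (16.5 to 23.4). Of the KO regions gained at day 23, 5720 (30.6%) overlapped those gained in EV.

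Whole chromosomes differed between the genotypes. The share of a library's covered bases on chromosome 13 was higher in KO in 15 of 15 combinations of mark and day, by 0.61 to 1.78 on the log2 scale, and that on chromosome 14 was lower in 15 of 15, by -0.30 to -1.57. Chromosomes 2 and 10 were also higher, and 11, 15 and 18 lower, in all 15. Among untreated cells, H3K36me3 was lower in KO at 198 and higher at 4 of 355 tested genes on chromosome 14, and higher at 63 and lower at 2 of 155 on chromosome 13. For H3K27ac on chromosome 14 the calls were 89 lower and 5 higher of 397, and for H3K4me3 32 lower and 6 higher of 479. Over all chromosomes the calls were 3098 of 10567 for H3K36me3, 1240 of 12220 for H3K27ac and 972 of 14794 for H3K4me3. Of these, 9.17, 18.2 and 23.5% were higher in KO. The H3K4me3 calls on chromosome 14 were thus close to their share over all chromosomes. MDGA2 and LRFN5 were higher in KO although chromosome 14 held a lower share of covered bases there. HOGA1 and PAX2 lie on chromosome 10.

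**Figure D3:**
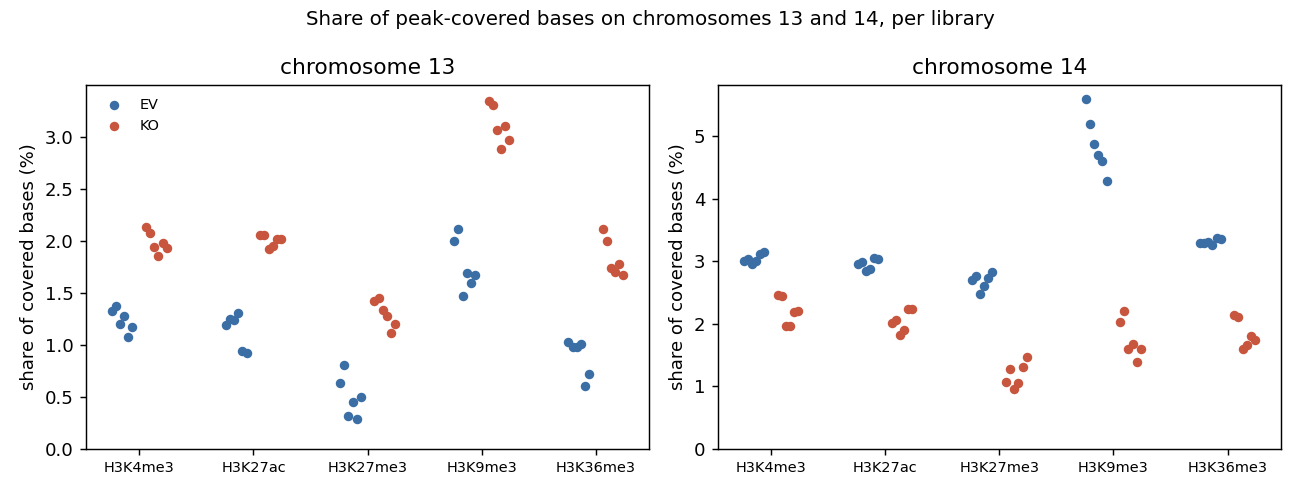
Share in percent of a library's peak-covered bases on chromosome 13 and chromosome 14, by mark, in EV (blue) and KO (red), with each point 1 of 60 libraries. All KO points lie above all EV points of the mark on chromosome 13 and below them on chromosome 14, and 0 libraries are out of place.

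Whether the change over days differed between EV and KO was tested with the limma interaction. It called 1628 genes for H3K4me3, 543 for H3K27ac, 5 for H3K27me3, 534 for H3K9me3 and 2017 for H3K36me3. PAX2 (H3K27ac, limma adjusted p = 0.000848), SLC17A3 (H3K4me3, 0.000591), HOXD10 (H3K36me3, 1.67e-05) and HOXA3 (H3K4me3, 0.00902) were among them, and the interferon-stimulated XAF1 (H3K36me3, 0.000362) and IFI44L (H3K36me3, 0.00136) as well. Leaving out each of the 12 libraries in turn gave 529 (without KO day 0 replicate 2) to 1827 H3K4me3 genes, 153 (without EV day 5 replicate 2) to 558 for H3K27ac, 0 (without KO day 0 replicate 1 or 2, with 638 and 684 at an unadjusted p under 0.05) to 26 for H3K27me3, 19 (without EV day 0 replicate 2) to 919 for H3K9me3 and 992 (without EV day 5 replicate 1) to 1729 for H3K36me3. At equal covered length the counts were 1163, 1114, 181, 281 and 811.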

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

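The tests of covered length and of time in culture were chosen only after the results were seen, whereas the interaction and the test of blood cell genes were set before.

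The change over days differed between EV and KO for many genes. The interaction of genotype and day called 1628 genes for H3K4me3, 543 for H3K27ac, 5 for H3K27me3, 534 for H3K9me3 and 2017 for H3K36me3. Without 1 library these ran from 529 (KO day 0 replicate 2), 153 (EV day 5 replicate 2), 0 (KO day 0 replicate 1 or 2, with 638 and 684 at an unadjusted p under 0.05), 19 (EV day 0 replicate 2) and 992 (EV day 5 replicate 1) up to 1827, 558, 26, 919 and 1729. At day 5 the covered length of 4 marks moved in opposite directions in the genotypes, in both replicates, which was not tested. On the log2 scale it changed by 0.33 in EV and -0.36 in KO for H3K4me3, by 0.45 and -0.17 for H3K27ac, by 0.35 and -0.83 for H3K9me3 and by 0.17 and -0.25 for H3K36me3.

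Of 73 combinations of gene and mark printed for a change after decitabine, 48 differed between the genotypes by the limma interaction test. They were picked as large changes within a genotype from the same libraries, which raises this share, and over all tested promoters 1628 of 14794 differed for H3K4me3. For kidney genes the interaction adjusted p was 0.000848 for PAX2 in H3K27ac and 0.0243 in H3K4me3, 0.000591 for SLC17A3 in H3K4me3 and 0.0128 in H3K27ac, 0.0324 for PDZK1 in H3K4me3 and 0.00493 in H3K27ac, 0.000421 for HOGA1 (H3K27ac), 0.0267 for CDH6 (H3K36me3), 0.00116 for VCAM1 (H3K36me3), and 0.00348 for CLDN2 in H3K4me3 and 0.00169 in H3K27ac. PAX2, SLC17A3, HOGA1 and CLDN2 were already higher in untreated KO than in EV cells, and the same untreated libraries enter both comparisons. For interferon-stimulated genes and their sensors it was 0.0220 for XAF1 in H3K4me3, 0.0262 in H3K27ac and 0.000362 in H3K36me3, 0.0212 for IFI6 (H3K27ac), 0.00136 for IFI44L (H3K36me3), 0.0117 for IFIH1 (H3K36me3), 0.00313 for IRF7 (H3K36me3), 0.0410 for GBP5 (H3K4me3) and 0.0106 for BATF2 (H3K4me3).

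Other genes that differed by the limma interaction test in H3K4me3 were HOXA3 (adjusted p = 0.00902), HOXD9 (0.00657), TWIST1 (0.00757), COL5A1 (0.0337), SIX3 (0.00643), BOLL (0.00538), KRT17 (0.00348), GRM7 (0.00498), KCNJ16 (0.0378) and GPR15 (0.00415). In H3K27ac these were TBX3 (0.0224), CHRDL2 (0.0131), TRIML2 (0.000848), FUT7 (0.00702), CDKN2C (0.00718), FSD2 (0.000848) and IL17B (0.0157). In H3K36me3 they were HOXD10 (1.67e-05), MYEOV (6.5e-05), ATF5 (0.00142) and TIMD4 (0.0267), and in H3K9me3 ELOA2 (0.0241), CCER2 (0.0450), ZNF722 (0.00991), ZNF776 (0.0496), ZNF614 (0.00991), ZNF595 (0.0105) and PRR20B (0.00667).

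Interferon-stimulated genes gained active marks by day 23 in both genotypes, MX2 from no H3K27ac in either. A larger covered length at day 23 predicts that the gain shrinks when libraries are trimmed to equal length. The mean H3K27ac gain of the list kept 90.9% of its size or more, over the members that still passed the filter after trimming. Members that fell below the filter dropped out, so this value cannot set covered length aside. Blood cells in the samples predict H3K36me3 over PTPRC, LCK, SPI1, CD3E, CD79A and ITGAM. These 6 bodies went from 0 to 2.44% in EV and 0.215% in KO, at most 6.71% of the gain of the list, and the highest was SPI1 at 9.17%. Because 0 untreated libraries were harvested at day 23, decitabine and time in culture cannot be told apart, and a biological response to the drug may be the source but stays a hypothesis.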

How the results depend on the processing

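Several alternatives were chosen only after the results were seen: the mean of both gene ends, chromosomes 13 and 14 left out, every alternative of the gene lists other than the preset correlation, and those of the share of gained regions near a gene end. All others were set before. Among 228 gene counts under an alternative, 162 stayed within 1.5 times the count reported and 66 did not, and with a library left out 207 of 360 did. Covered length kept its direction and side of the threshold in 23 of 30 cases and in 90 of 100 with a library left out. The gene lists did so in 80 of 108 and 265 of 324. Of the 125 named gene results, 87 were called under every alternative that could test them, 38 lost their call under at least 1, and none reversed. Only 67 of the 87 could be tested under every alternative, and the other 20 fell below the filter in at least 1: equal covered length gave a value for 111 of the 125 results, stricter peaks for 120, KO day 0 replicate 1 or 2 left out for 118 and EV day 23 replicate 1 or 2 left out for 124. The 21 named results removed after the alternatives had been run had all lost a call (14 to a library left out, 15 to another alternative), so of the 146 taken up 87 were stable and 59 not. The removed results were DLL4, HOXA5, RIGI in EV and KO, TRPM2, PAPLN, C1QTNF2, PCDHB10 in both of its comparisons, FBXO39, IFIT1, PCDHB5, FOXD4L5, PRSS53, BTG2, COL1A1, UNC13D, PINLYP, IL1A, CNTF and SPP1. No read counts were at hand, so a difference in depth cannot be separated from a difference in covered length, and weak peaks of shallow libraries may be missing: at equal covered length 17 of 30 gene counts moved. Except where stated, the cause was not tested.

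The counts of called genes that moved beyond 1.5 times with stricter peaks were for H3K27me3 371 (KO against EV), 347 (EV day 5), 56 (KO day 5), 55 (KO day 23) and 221 (interaction). For H3K9me3 they were 231 (KO against EV), 1020 (EV day 5), 11 (EV day 23), 570 (KO day 5) and 246 (interaction). For H3K36me3 they were 345 (KO against EV), 197 (EV day 23), 373 (KO day 5), 330 (KO day 23) and 489 (interaction). Equal covered length gave for H3K4me3 637 (KO against EV), 1009 (EV day 23) and 879 (KO day 23). For H3K27ac they were 1797 (EV day 5) and 1114 (interaction). For H3K27me3 they were 582 (KO against EV), 147 (EV day 5), 272 (KO day 23) and 181 (interaction). For H3K9me3 they were 277 (EV day 5), 343 (KO day 23) and 281 (interaction). For H3K36me3 they were 1267 (KO against EV), 1032 (EV day 23), 676 (KO day 5), 890 (KO day 23) and 811 (interaction). The narrower promoter window gave for H3K4me3 565 (EV day 5), 1314 (EV day 23) and 1016 (KO day 23). For H3K27ac it was 287 (EV day 5). For H3K27me3 they were 72 (EV day 5), 271 (EV day 23) and 92 (interaction). The mean of both gene ends gave for H3K27ac 920 (EV day 5) and 850 (interaction). For H3K27me3 it was 2 (interaction). The arcsine square root gave for H3K27me3 3 (EV day 5), 25 (KO day 5) and 3 (interaction). For H3K9me3 they were 96 (EV day 23) and 161 (interaction). For H3K36me3 it was 211 (EV day 5). Testing without a filter gave for H3K27me3 111 (EV day 5) and 148 (interaction). For H3K9me3 they were 1376 (KO against EV), 3516 (EV day 5), 107 (EV day 23), 2302 (KO day 5), 1575 (KO day 23) and 1518 (interaction). Leaving out chromosomes 13 and 14 gave 11 for the H3K27me3 interaction and 24 for H3K9me3 in EV at day 23, with fewer genes tested. The cause of the other moves was not tested.

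Each library left out in turn gave, in the order KO against EV, EV day 5, EV day 23, KO day 5, KO day 23 and interaction, the following counts. H3K4me3 had 392 to 1066, 238 to 1036, 998 to 2502, 646 to 3151, 533 to 1646 and 529 to 1827. H3K27ac had 373 to 1233, 83 to 515, 176 to 515, 176 to 623, 461 to 1013 and 153 to 558. H3K27me3 had 380 to 1170, 1 to 71, 112 to 515, 5 to 118, 66 to 401 and 0 to 26. H3K9me3 had 122 to 475, 70 to 2266, 0 to 48, 152 to 1377, 57 to 632 and 19 to 919. H3K36me3 had 1551 to 3302, 78 to 384, 1210 to 2470, 701 to 1598, 951 to 1629 and 992 to 1729. With a library left out its group holds 1 library, and the rises above the reported counts have a cause that was not tested. The log2 KO to EV ratio of covered length ran from -0.41 to -0.30 for H3K4me3 and -0.90 to -0.61 for H3K9me3, and the day 23 ratio of H3K36me3 from -0.13 to 0.0183, reversed without KO day 23 replicate 1. The genic share of H3K36me3 ran from 0.618 to 1.47 points and H3K27me3 over H3K36me3-covered bodies from -0.221 to 0.0177, reversed without EV day 23 replicate 2, and H3K9me3 there from -1.24 to -0.314. Gained H3K4me3 regions numbered 15256 to 31078 (EV day 5), 23715 to 42176 (EV day 23), 6107 to 17868 (KO day 5) and 20424 to 39512 (KO day 23), and lost regions 4562 to 7444, 3880 to 6745, 8353 to 11563 and 3851 to 6096, since a single replicate then sufficed. Their shares near a gene end were 5.95 to 6.40, 8.32 to 9.41, 5.99 to 7.40 and 6.81 to 8.20%. The limma camera adjusted p ran from 0.0487 to 0.116 for interferon H3K27ac at day 23 in both genotypes and from 0.439 to 0.996 in EV at day 5, where the mean change became 0.378 points (0.996) without EV day 0 replicate 1. It ran from 0.0544 to 0.281 for renal H3K27ac in KO at day 5 and day 23, and from 0.0612 to 0.191 for interferon H3K36me3 in KO at day 23.

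With stricter peaks the log2 KO to EV ratio of covered length no longer passed for 3 marks, although as a mean over the 3 days it was larger in size than with all peaks. The exact permutation p was 0.213 for H3K27me3 (-1.13), 0.0556 for H3K9me3 (-0.94) and 0.120 for H3K36me3 (-0.65). At day 0 alone, stricter H3K36me3 and H3K9me3 peaks covered no less on average in KO than in EV. Stricter peaks raised the genic share of H3K36me3 to 2.30 points (exact permutation p = 0.00926) and turned H3K27me3 over H3K36me3-covered bodies to 0.00957 points. They left 5726, 10977, 1615 and 8873 gained and 1538, 1479, 4024 and 1831 lost H3K4me3 regions (EV day 5, EV day 23, KO day 5, KO day 23), fewer because fewer peaks remained, with 7.21, 10.8, 8.48 and 8.87% near a gene end. Interferon H3K27ac in EV at day 5 changed sign to 0.849 points (limma camera adjusted p = 0.779, against -10.2 points and 0.518 at equal covered length), interferon H3K36me3 in KO at day 23 had 0.0667, and 0 lists were called for H3K36me3. Under equal covered length H3K27me3 and H3K9me3 over H3K36me3-covered bodies reversed to 0.0880 and 0.479 points (exact permutation p = 0.00926). Trimming takes more from the EV libraries on average, so this reversal cannot show a spread of either mark in KO. Gained regions became 374, 229 and 502 (EV day 5, EV day 23, KO day 23) and lost regions 1398, 1587, 329 and 1167, with 8.82, 37.99 and 19.7% of the gained ones near a gene end. Germline H3K4me3 in EV at day 23 reversed to -0.634 points (limma camera adjusted p = 0.794). Limma camera gave 0.0519 for renal H3K27ac in KO at day 23, 0.0217 for interferon H3K36me3 in EV at day 23 and 0.0479 for renal H3K36me3 in KO at day 5, with 4 lists called for H3K36me3. For the number of peaks, the log2 ratio was -0.32 for KO against EV in H3K4me3 (exact permutation p = 0.00926) and +0.28 for day 23 in H3K36me3 (0.0556). The cause of these changes was not tested.

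The preset correlation lowered limma camera values by construction, because genes of a list are then taken as nearly independent. For H3K4me3 it gave 3.53e-09 and 1.14e-15 for interferon-stimulated genes at day 23 (EV, KO), 2.26e-10 and 0.000237 for developmental and germline genes (EV day 23), 1.11e-07 for HOX (EV day 5) and 0.000457 for renal genes (KO day 23). For H3K27ac it gave 0.00674 for interferon-stimulated genes (EV day 5), 0.0331 for renal genes (EV day 23) and 0.00107 for HOX (KO against EV). For H3K9me3 it gave 1.26e-21, 3.11e-19 and 0.00986 for KRAB genes (KO day 5, KO day 23, EV day 5) and 3.61e-14, 0.0384 and 1.23e-07 for protocadherins (KO against EV, EV day 5, KO day 5). For H3K36me3 it gave 1.01e-16 for interferon-stimulated genes (EV day 23), 0.00185 and 0.0258 for renal genes (KO day 5, KO day 23) and 0.0482 for protocadherins (KO against EV). Lists called numbered 21, 18, 5, 22 and 23 for H3K4me3, H3K27ac, H3K27me3, H3K9me3 and H3K36me3.

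With the replicate number as a block, although the numbers were not taken to pair the libraries, the counts were 895 for the H3K27ac interaction and 50 and 2 for H3K27me3 (EV day 5, interaction). For H3K9me3 they were 939 (KO against EV), 341 (EV day 23), 1792 (KO day 5), 1078 (KO day 23) and 1622 (interaction). The block gave a log2 KO to EV ratio of covered length of -0.35 for H3K4me3 (exact permutation p = 0.03125) and -0.75 for H3K9me3 (0.0625), and 1.05 points for the genic share of H3K36me3 (0.03125). Limma camera with the block gave 0.0502 for renal H3K27ac in KO at day 5 and day 23 and 0.0738 for interferon H3K36me3 in KO at day 23. The block changed no other call of a list, covered length or named gene, and the other gene counts stayed within 1.5 times. No block was possible for gained and lost regions, which come from no test.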

Other observations

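The tests of chromosome copies, of covered length, of exchanged labels and of remaining SETD2 function were chosen only after the results were seen, as was the equal covered length of the lists.

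Clustered protocadherins, a family of neuronal cell adhesion genes, had a lower mean H3K9me3 cover in untreated KO: 45 bodies averaged 20.7% in EV and 2.25% in KO at day 0, with 8 lower and 0 higher (11 lower adjusted over the list alone). They averaged 38.4% in EV at day 5 (37 up, 0 down, 38 up adjusted over the list alone) and 21.1% in KO at day 5 (10 up, 0 down, the same adjusted over the list alone). Over 30 tested bodies mean H3K36me3 was lower in KO, 18.5% in EV against 6.31%, with 22 lower and 0 higher, the same adjusted over the list alone. Members of a clustered family share peaks, so these counts do not stand for as many separate changes. Trimmed to equal covered length, the H3K9me3 difference at day 0 was -11.7 points and the H3K36me3 difference -6.08, the latter -6.04 with stricter peaks. None of these stood apart by limma camera (adjusted p = 0.996, 0.996 and 0.996 for H3K9me3 and 0.973 for H3K36me3). KRAB zinc finger genes of chromosome 19 had a lower mean H3K9me3 cover after day 0 in KO, from 52.6% to 32.8% at day 5 (4 up and 136 down of 237, 7 and 160 adjusted over the list alone) and to 34.6% at day 23 (0 up and 108 down, 133 down adjusted over the list alone). Camera gave 0.996 in limma for both, and at equal covered length the mean changes were -5.23 and -2.44 points, and without KO day 23 replicate 1 that of day 23 was -11.7. In EV at day 5 the mean of the list went from 54.7 to 65.9% (69 up, 1 down, 42 up adjusted over the list alone), and changed by 5.10 points at equal covered length. Camera placed the list below other genes, so mean and test differ in sign.

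Developmental transcription factors had a higher mean H3K4me3 cover in EV at day 23, from 26.8 to 49.4% over 63 promoters (34 up, 0 down, 39 up adjusted over the list alone, limma camera adjusted p = 0.805), with 6.49 points left at equal covered length. Germline genes also had a higher mean there, 35.3 against 14.8% over 36 promoters (19 up, 1 down, 20 and 1 adjusted over the list alone, limma camera adjusted p = 0.841). Their mean changed by -0.634 points at equal covered length, where only 13 promoters were tested, and by 13.3 points without EV day 23 replicate 2. HOX promoters in untreated KO had 46.1% H3K27ac against 66.4% in EV over 32 genes (13 lower, 0 higher, 16 lower adjusted over the list alone, limma camera adjusted p = 0.438). Renal epithelial promoters had a lower mean H3K4me3 cover after day 0 in KO, 39.7 to 19.7% at day 5 over 23 genes (10 down, 0 up, 11 down adjusted over the list alone, limma camera adjusted p = 0.985) and to 25.7% at day 23 (10 down, 3 up, 10 down and 4 up adjusted over the list alone, 0.821). The changes of -20.0 and -14.0 points became -12.8 and -6.37 without KO day 0 replicate 2, and the latter -22.1 at equal covered length. Their H3K36me3 at day 23 was 20.4% (6 down, 2 up, 9 down and 3 up adjusted over the list alone, limma camera adjusted p = 0.908), a change of -28.6 points that was -46.9 over 10 bodies with stricter peaks. Of 20 antigen presentation genes, 7 fell in H3K4me3 in KO at day 5 (8 adjusted over the list alone, limma camera adjusted p = 0.985). TAPBP went from 74.4 ± 5.55 to 17.5 ± 24.7% (limma adjusted p = 0.0144), and TAP1 and PSMB9, which share a promoter region, from 49.9 ± 11.9 to 0% (0.0152 and 0.0139). Leaving out a library ended these calls: TAPBP had 0.0530, 0.101 and 0.0674 without KO day 0 replicate 1, KO day 0 replicate 2 and KO day 5 replicate 1, at -60.9, -53.0 and -39.5 points. TAP1 had 0.116 and 0.0677, and PSMB9 0.109 and 0.0633, without KO day 0 replicate 2 and KO day 5 replicate 1, at -41.5 and -49.9 points for both. With equal covered length TAP1 and PSMB9 had 0.0771 at -45.45 points, and the lowest values over the alternatives were 0.002, 0.0038 and 0.00338.

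The other lists are given by the mark and comparison with most members changed, with the limma camera adjusted p. RNA-sensing genes had 6 up and 1 down of 18, the same adjusted over the list alone, for H3K36me3 in EV at day 23 (0.317, and 0.133 as the lowest of all its tests). Genes hypermethylated in renal cell carcinoma had 14 up and 1 down of 38 for H3K4me3 in EV at day 23 (18 and 1 adjusted over the list alone, 0.985). Hypoxia genes had 2 up and 8 down of 26 (the same adjusted over the list alone, 0.973) and p53 genes 7 up and 1 down of 27 (8 and 1 adjusted over the list alone, 0.317) for H3K36me3 in KO against EV. Splicing factors had 2 up and 6 down of 61 for H3K36me3 in EV at day 23 (0 and 2 adjusted over the list alone, 0.994). For H3K4me3 in KO at day 5, chromatin machinery had 1 up and 9 down of 45 (1 and 10 adjusted over the list alone, 0.985), cell cycle genes 0 and 9 of 39 (0 and 10 adjusted over the list alone, 0.985) and ribosomal protein genes 0 and 10 of 63 (0 and 7 adjusted over the list alone, 0.985). Lineage markers for H3K4me3 in EV at day 23 had, for blood, 2 up of 12 (3 up and 1 down adjusted over the list alone), hepatocyte and neuron 3 up of 13 (the same adjusted over the list alone), fibroblast and endothelial 3 up of 10 (4 up and 1 down adjusted over the list alone), each at 0.985.

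H3K36me3 stayed over many gene bodies in the libraries labelled KO. Signal of another kind in place of H3K36me3 predicts no rise along genes, but the excess of the far over the near part of long genes in untreated KO was 0.803 of that in EV (13.5 and 12.3 points against 16.5 and 15.6). Exchange of single libraries predicts libraries on the wrong side of the chromosome 14 difference, and 0 of 60 were. Cells with working SETD2 within the KO population predict the genes marked in EV, and 71.5% of these were covered in KO. A general weakening could give the same share, so this cannot be told apart from remaining enzyme activity or from how peaks are called in each library without counts, and a biological explanation was not tested further.

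Chromosomes 13 and 14 differed between EV and KO in the share of covered bases of both active and silent marks. Different covered length predicts that H3K36me3 on chromosome 13 lies among the other autosomes once libraries are trimmed, but at equal length it differed by 33.4 points, against -18.3 (chromosome 14) to 11.5 (chromosome 4) on the other autosomes and 22.8 on chromosome X. A different number of chromosome copies predicts the same sign in every mark, which 15 of 15 combinations of mark and day had on both chromosomes, but these were picked for that sign, and chromosomes 2, 10, 11, 15 and 18 had it in all 15 too. On chromosome 13 in untreated KO, H3K27me3 was higher at 8 and lower at 8 genes with a mean of 12.6 points at equal length, and H3K9me3 higher at 20 and lower at 6 with a mean of -18.1 points over 25 genes at equal length, so copy number cannot be told apart from other sources without counts. With both chromosomes left out only the H3K27me3 interaction count (5 to 11) and the H3K9me3 count of EV at day 23 (37 to 24) moved beyond 1.5 times, and a role of SETD2 was not tested, since the labels do not tell how many clones each genotype stands for.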
